A study of Mus musculus with 9 samples.

How the data were processed

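RNA was measured in 9 brain libraries of male C57BL/6J mice, 3 from untreated controls, 3 from mice given MPTP and 3 from mice given MPTP and curcumin. Groups and replicate numbers were taken from the labels. The labels name no brain region and do not say whether a library came from 1 animal or a pool, so p-values here measure only the spread between these samples, which may be technical.

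Per the series' design text, libraries were made with a VAHTS Universal V6 kit and read as 150 bp paired ends on an Illumina NovaSeq instrument. Reads were cleaned with fastp, aligned with HISAT2 and counted per gene with HTSeq-count, per the labels. The genome build was mm10, per the submitters' processing notes, which also name R 3.2.0. Versions of the other tools, the annotation release and the strand setting are not given in the sources used here. Without the strand setting, reads of overlapping or antisense genes cannot be separated. The deposited read counts are whole numbers per gene with no normalization. The deposited FPKM values, computed by the authors, equal the counts divided by a length per gene and by the library total, with a largest relative difference of 9.37e-09 between libraries. The design text states that the authors tested for differences with DESeq2, at a q-value threshold of 0.05 and a fold threshold of 2.

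The count table held 18328 genes, with 0 entries that name no gene. Of their NCBI gene numbers, 18212 were found in the RefSeq table of assembly GRCm38.p6, the reference called mm10, and 116 were not. Coordinates come from that table. The table held 0 mitochondrially encoded genes.

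The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with all 9 libraries in a single fit by group and no covariate. Genes were kept by filterByExpr, which left 15461 genes and removed 2867 that held 0.0188% of the counts. Library sizes were scaled by TMM. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and the F statistic. CPM values are scaled by the same TMM factors. The biological coefficient of variation was 14.3%.

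Before the data were examined, 39 gene lists were fixed that cover brain regions, cell types, signalling pathways, stress responses and signs of RNA quality. Lists with at least 3 tested members were tested with camera of limma 3.58.1 on voom-weighted values, with a preset inter-gene correlation of 0.01 and adjustment over the lists. That left 37 lists. The pituitary list had 1 tested member and the mitochondrially encoded list had 0, so both have no result. Each list was also tested with the correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance in 1 direction. Members were also adjusted over the list alone.

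Named genes follow a rule fixed at the same time. It takes up to 10 called genes per direction with a mean log2 CPM of at least 1 and no overlap between groups, up to 4 members with the smallest p from each called list, and 13 genes of the dopamine and PI3K-AKT systems and of glia in every comparison. Some of these genes are not reported here. The 4 genes called here lie below that level, so they fall outside the rule, and they were chosen after their values were seen. The pairs Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, and Hspa1a and Hspa1b are near-identical copies whose reads the counting may have divided or dropped, so their values are uncertain.

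On simulated counts with 200 changed genes, the test recovered 56.7% of genes changed 1.5-fold, 79.1% of those changed 2-fold and 100% of those changed 4-fold in the comparison of MPTP with control. For MPTP + curcumin against MPTP the shares were 58.2%, 86.6% and 95.5%, and against control 61.2%, 83.6% and 98.5%. False calls made up 6.1%, 7% and 5.5% of all calls. A simulated list of 18 genes raised 1.5-fold was called with an estimated correlation in each comparison, at adjusted p-values of 0.000201, 0.000175 and 0.00357. The simulated genes varied independently of one another, and the 200 changed genes left out those with the lowest counts. In MPTP against control the estimated correlation was 0.442 in the glucocorticoid list and 0.606 in the erythroid list. The simulation therefore does not show that such a shift would be found in lists whose genes move together.

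Library totals ran from 34858874 to 38951963 counts. A gene with no reads in a library could still stand at up to 3 counts, which is 0.077 to 0.0861 CPM over the 9 libraries. Ratios of summed counts carry exact 95% binomial intervals (Clopper-Pearson). Intervals and floors cover counting error only.

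Alternatives fixed in advance were another scaling (RLE), library totals only, no filter on low counts, at least 50 counts in 3 libraries, DESeq2 1.42.0, limma voom, a fit of only the 6 libraries compared, robust estimation, FPKM with pseudocounts of 1 and 0.1, the replicate number as a block, and each library left out in turn. FPKM fits kept genes with at least 0.5 in 3 libraries, and their fold changes are on the log2(FPKM + pseudocount) scale. A further pair of settings was chosen after seeing the data: leaving out the 3 libraries with the highest counts of hypothalamic and midbrain markers (control 3, MPTP 3 and MPTP + curcumin 1), and the mean level of the dopaminergic list as a covariate. Lists of colon and liver genes and the KEGG pathways named in the deposited annotation were also added after seeing the data. Correlations across libraries were tested by exact permutation with scipy 1.17.1 and numpy 2.4.6 in Python 3.11.15, and plots were drawn with matplotlib 3.10.9.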

Results

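Messenger RNA levels were measured by sequencing in brain tissue of male C57BL/6J mice, from a series of 30 mice. Their age is given as 8 weeks, and with 7 weeks of curcumin in the curcumin group this may not be the age at death. The control group had no treatment by its label. The MPTP group received 20 mg/kg of MPTP, a toxin whose metabolite damages dopaminergic neurons, by intraperitoneal injection every 3.5 days, for 10 injections over 5 weeks. Each injection came with 250 mg/kg of probenecid, which slows the clearance of that metabolite. The third group received the same injections and 60 mg/kg of curcumin, a plant polyphenol, by gavage each day for 7 weeks. Each group had 3 libraries. Library totals were 36156539, 37748198 and 34874875 counts in control, 35453480, 35805066 and 35362343 in MPTP, and 38951963, 34858874 and 35916195 in MPTP + curcumin. Between 16783 and 17115 genes had at least 1 count in a library.

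Libraries of different groups correlated about as closely as libraries of 1 group. Correlations of log2 CPM across genes, which are not independent replicates, ran from 0.979 to 0.989 within groups and from 0.975 to 0.987 between groups. No pair of libraries agreed within sampling noise, the smallest chi-square per degree of freedom being 5.15. Markers of brain regions differed widely between libraries of a group. Slc6a3, the dopamine transporter of midbrain dopaminergic neurons, had 28, 294 and 1180 counts in the control libraries, 318, 407 and 678 in MPTP, and 1710, 45 and 47 in MPTP + curcumin. Pmch, a peptide gene of the lateral hypothalamus, had 385 counts in control 3, 1690 in MPTP 3 and 291 in MPTP + curcumin 1, and at most 27 in each of the other libraries. These 3 libraries also held the highest counts of Hcrt, the hypothalamic orexin gene.

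**Figure D1:**
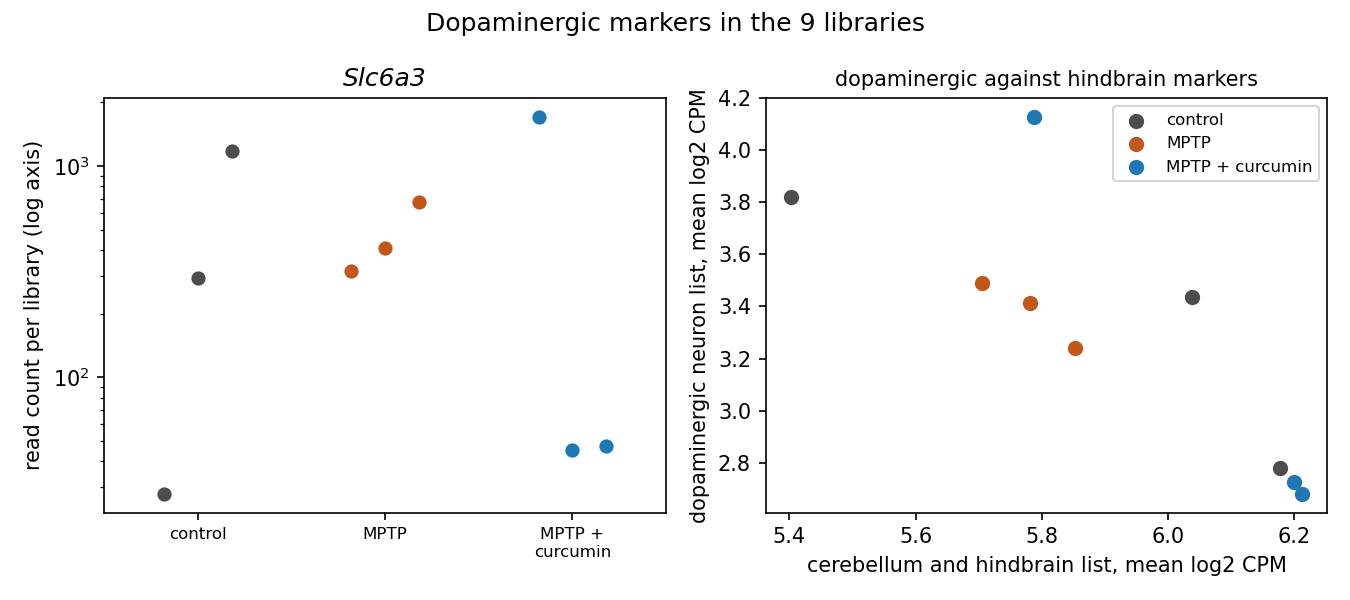
Read counts of Slc6a3 in each library on a log axis (left), and the mean log2 CPM of the dopaminergic neuron list against that of the cerebellum and hindbrain list (right), 1 point per library, coloured by group. Slc6a3 ranged from 28 to 1180 counts within the control group and from 45 to 1710 within MPTP + curcumin.

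The comparison of MPTP with control asks how brain gene expression differed in this mouse model of Parkinson disease. Genes induced by glucocorticoid hormones and immediate early genes, which neuronal activity switches on within minutes, were lower in the MPTP libraries as lists, with median log2 fold changes of −0.56 and −0.67 (3 libraries per group; adjusted p = 0.354 with an estimated correlation for both). Chaperones and other genes of the unfolded protein response were lower by a median of −0.26, and genes of red blood cells were higher by a median of 1.00. Both of these lists also had adjusted p = 0.354 with an estimated correlation. No gene passed edgeR's test over all genes, and the list of dopaminergic neuron markers was not called.

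Of 16 glucocorticoid-responsive genes, 15 had a negative log2 fold change, and the list fell (limma camera adjusted p = 2.62e-12, adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone, 10 members were lower. Pdk4, a kinase that restrains pyruvate oxidation, stood at 11.1 ± 0.906 CPM in MPTP and 18.9 ± 0.387 in control (SD, n = 3 each), a log2 fold change of −0.77 ± 0.13 (SE). The log2 fold changes were −1.37 ± 0.28 for Zbtb16, a transcription factor, −0.87 ± 0.17 for Cdkn1a, a cell cycle inhibitor, and −0.43 ± 0.08 for Errfi1, a feedback inhibitor of the EGF receptor. The count adjusted over the list alone was 5 without control 3, with a median of −0.43, and 6 without MPTP 2, with a median of −0.54. Zbtb16 and Dio2, which activates thyroid hormone, passed the test over all genes without control 2.

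The immediate early list fell as well, with 16 of 17 members negative (camera adjusted p = 1.54e-09, adjusted p = 0.354 with an estimated correlation). Adjusted over the list alone, 6 members were lower, and 2 were without MPTP 1 or without MPTP 2 (medians −0.61 and −0.52). Nr4a3, an orphan nuclear receptor, had a log2 fold change of −1.80 ± 0.36 (SE) and Fosl2, a subunit of AP-1, of −0.89 ± 0.20. Fos stood at 8.96 ± 1.13 CPM in MPTP and 25.8 ± 21.4 in control (SD, n = 3 each). Its counts were 1822, 558 and 420 in the control libraries and 293, 301 and 372 in MPTP. Control 1 also held 812 counts of Hspa1a and 1048 of Hspa1b, a pair of heat shock genes, against at most 354 and 388 in each of the other libraries. Without control 1 the median of the list was −0.36 and 4 members were lower adjusted over the list alone. The unfolded protein and integrated stress response list had 15 of 16 members negative and fell (camera adjusted p = 8.58e-08, adjusted p = 0.354 with an estimated correlation). Its members Xbp1, a transcription factor of that response, and Pdia4, a chaperone, had log2 fold changes of −0.64 ± 0.18 and −0.62 ± 0.18. Adjusted over the list alone, 7 members were lower, and 0 were without any single one of control 1, control 3 or the MPTP libraries.

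All 7 erythroid genes were positive, the list rose (camera adjusted p = 1.4e-11, adjusted p = 0.354 with an estimated correlation), and 5 members were higher adjusted over the list alone. Hbb-bs, a beta globin, stood at 567.9 ± 96.9 CPM in MPTP and 286.1 ± 31.7 in control (SD, n = 3 each), a log2 fold change of 0.99 ± 0.20 (SE). That of Hba-a1, an alpha globin, was 1.00 ± 0.19, and that of Alas2, the first enzyme of haem synthesis in red cells, was 1.19 ± 0.26. The ependymal cell list rose with all 9 members positive and a median of 0.35 (adjusted p = 0.000135, adjusted p = 0.354 with an estimated correlation). Ccdc153, a gene of ciliated cells, had a log2 fold change of 0.91 ± 0.25 and was the 1 member higher adjusted over the list alone, which it was not without control 1, control 2, MPTP 1 or MPTP 3 (list medians 0.44, 0.24, 0.36 and 0.34).

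**Figure D2:**
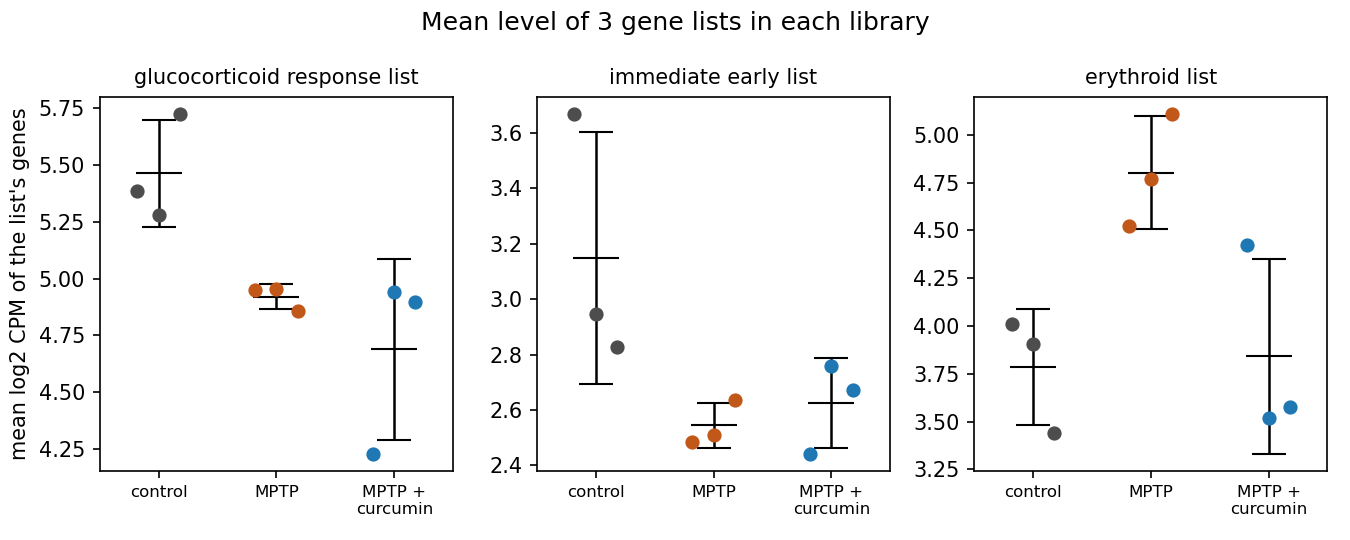
Mean log2 CPM of the genes of the glucocorticoid response, immediate early and erythroid lists in each library (points), with the group mean and SD over 3 libraries (bars). The glucocorticoid list lay between 5.28 and 5.73 in control and between 4.23 and 4.95 in the other libraries, and control 1 had the highest immediate early value, 3.67.

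Smaller shifts were found in lists of housekeeping and neuronal genes. The cytosolic ribosomal protein list rose, with all 44 members positive and a median of 0.15 (camera adjusted p = 1.45e-11, adjusted p = 0.6 with an estimated correlation). Without MPTP 3 its median was 0.10. The respiratory complex I list rose by a median of 0.07 (adjusted p = 0.00684, adjusted p = 0.895 with an estimated correlation). The call was lost without control 2 (median 0.03) and without MPTP 3 (0.04). The synapse list fell by a median of −0.09 (adjusted p = 0.00329, adjusted p = 0.6 with an estimated correlation), and lost its call without control 2 (median −0.10, adjusted p = 0.0505). Bsn, a scaffold of the presynaptic zone, had a log2 fold change of −0.32 ± 0.15. Homeostatic microglia genes rose by a median of 0.13 (adjusted p = 0.00846, adjusted p = 0.743 with an estimated correlation), with Cx3cr1, the fractalkine receptor, at 0.31 ± 0.12 and P2ry12, a purine receptor, at 0.36 ± 0.14. That call was lost without control 2 (0.07) and MPTP 3 (0.03), and the median was 0.22 without control 3. Cholesterol synthesis genes rose by 0.10 (adjusted p = 0.0139, adjusted p = 0.743 with an estimated correlation), a call lost without control 3 (0.05) and MPTP 3 (0.01). Apoptosis and p53 genes fell by −0.10 (adjusted p = 0.0132, adjusted p = 0.354 with an estimated correlation), a call lost without control 3 (−0.03). Of the apoptosis genes, 2 were lower adjusted over the list alone, and 1 without control 1, 2 or 3, MPTP 1 or MPTP 3 (list medians −0.08, −0.15, −0.03, −0.09 and −0.14). The members with the smallest p were Cdkn1a and Bcl2l1, an inhibitor of apoptosis (−0.30 ± 0.08). In the ribosomal, complex I, synapse, microglia and cholesterol lists 0 members passed when adjusted over the list alone, and 1 cholesterol gene did without control 2 (list median 0.14).

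The series title places curcumin's effect in the PI3K-AKT pathway, which carries growth factor signals for survival. The PI3K-AKT core list had 30 of 34 members negative in MPTP against control and fell by a median of −0.08 (camera adjusted p = 0.000519, adjusted p = 0.6 with an estimated correlation). Without control 2 the median was −0.04 and without MPTP 3 it was −0.05, with 0 members lower adjusted over the list alone in either case or with all libraries. Pik3cd, a catalytic subunit, had a log2 fold change of −0.32 ± 0.12 (SE), Foxo3, a transcription factor that AKT holds in the cytoplasm, of −0.24 ± 0.11, and Irs2, an insulin receptor substrate, of −0.20 ± 0.09. Akt1 was at −0.07 ± 0.07, Akt2 at −0.03 ± 0.10, Pik3ca at −0.09 ± 0.07 and Pik3r1 at −0.02 ± 0.08. The list of its ligands and receptors had a median of −0.01 (adjusted p = 0.635).

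Dopaminergic markers did not pass as a list, with 11 of 15 members negative and a median of −0.12 (camera adjusted p = 0.534). Without control 1 the median was −0.23 and the list was called (adjusted p = 0.0318). That call used the preset correlation, and with an estimated one camera's adjusted p over all libraries was 0.904. Th, the rate-limiting enzyme of dopamine synthesis (NCBI gene 21823, chromosome 7, 142892779 to 142899995 in mm10), had 28.6 ± 3.55 CPM in MPTP and 26.2 ± 9.74 in control (SD, n = 3 each), a log2 fold change of 0.13 ± 0.32 (SE). Slc6a3 (NCBI gene 13162, chromosome 13, 73536128 to 73578672) had 13.0 ± 5.09 and 14.2 ± 17.5 CPM, a log2 fold change of −0.12 ± 1.19. The log2 fold changes were −0.04 ± 0.26 for Slc18a2, the vesicular monoamine transporter, and 0.06 ± 0.20 for Ddc, the decarboxylase that makes dopamine. Gfap, an astrocyte filament, was at 0.01 ± 0.16 and Aif1, a microglial marker, at 0.46 ± 0.27.

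The edgeR test called 0 of 15461 genes in MPTP against control, 957 had an unadjusted p under 0.05 where chance gives 773, and the smallest adjusted p was 0.117. DESeq2 called 38 genes, 11 of them over 2-fold, and limma voom called 0. The groups did not overlap in 2523 genes, 16.3%, where chance gives 10%. Without control 2 the count was 2, without MPTP + curcumin 1, which shares the estimate of the spread, it was 17, and without control 3, MPTP 3 and MPTP + curcumin 1 together it was 21. Of 37 lists 12 were called, 6 higher and 6 lower, and 0 with an estimated correlation or with fry.

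**Figure D3:**
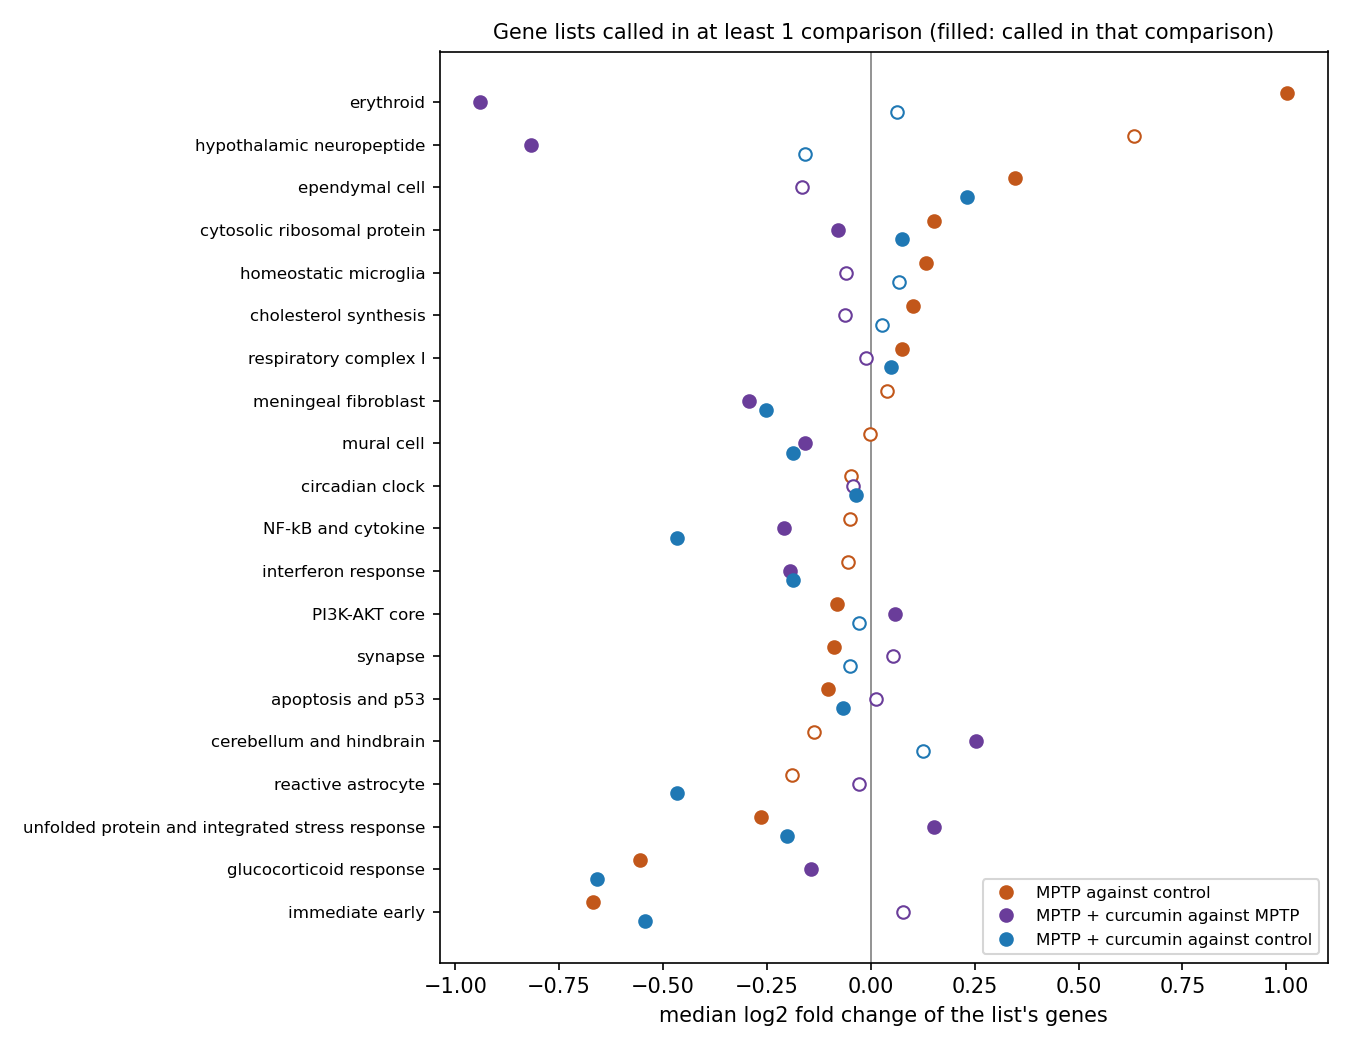
Median log2 fold change of the genes of each list called in at least 1 comparison, by comparison, with filled points where camera called the list at an adjusted p under 0.05. The erythroid list lay at 1.00 in MPTP against control and at −0.94 in MPTP + curcumin against MPTP, which share the MPTP libraries. The glucocorticoid list was lower in both comparisons against control, which share the control libraries.

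The comparison of MPTP + curcumin with MPTP asks how curcumin given alongside the toxin altered expression. Zg16 and Lypd8, known from the epithelium of the colon, and Car1, known from colon and from red blood cells, were lower in the MPTP + curcumin libraries and were the 3 genes called. Red blood cell genes, which were higher in MPTP than in control, were lower by a median log2 fold change of −0.94 (adjusted p = 0.254 with an estimated correlation). MPTP against control uses the same MPTP libraries, so chance alone favours opposite directions of genes and lists in these comparisons. The PI3K-AKT core list was higher by a median of 0.06 (adjusted p = 0.815 with an estimated correlation), a call that several single libraries decided. The list of dopaminergic neuron markers was not called.

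Zg16, a lectin of intestinal mucus (NCBI gene 69036, chromosome 7, 127050156 to 127052675), had 2.65 ± 0.283 CPM in MPTP (SD, n = 3) and 0 counts in all 3 MPTP + curcumin libraries. It was at least 32.0-fold lower, against a floor of 3 counts per library or 0.0827 CPM (edgeR adjusted p = 0.001). Lypd8, which keeps bacteria away from the gut wall (NCBI gene 70163, chromosome 11, 58379032 to 58390541), had 3.63 ± 0.812 CPM in MPTP and 0 counts with curcumin, at least 43.9-fold lower (adjusted p = 0.00312). Car1, carbonic anhydrase 1 (NCBI gene 12346, chromosome 3, 14766214 to 14808365), had 236 counts in the MPTP libraries and 2 with curcumin, a ratio of 119 (95% interval 32.7 to 991; adjusted p = 0.0456). The Car1 call was lost without any single one of the 6 libraries, with adjusted p from 0.0594 to 0.373. It was also lost with limma voom (0.0612) and with the replicate number as a block (0.136). The log2 fold change of Car1 was −9.31 without MPTP + curcumin 3, which held the 2 curcumin counts. Without any other single library it ran from −6.12 to −6.81. Each of the 3 genes was lower in 3 of 3 libraries.

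**Figure D4:**
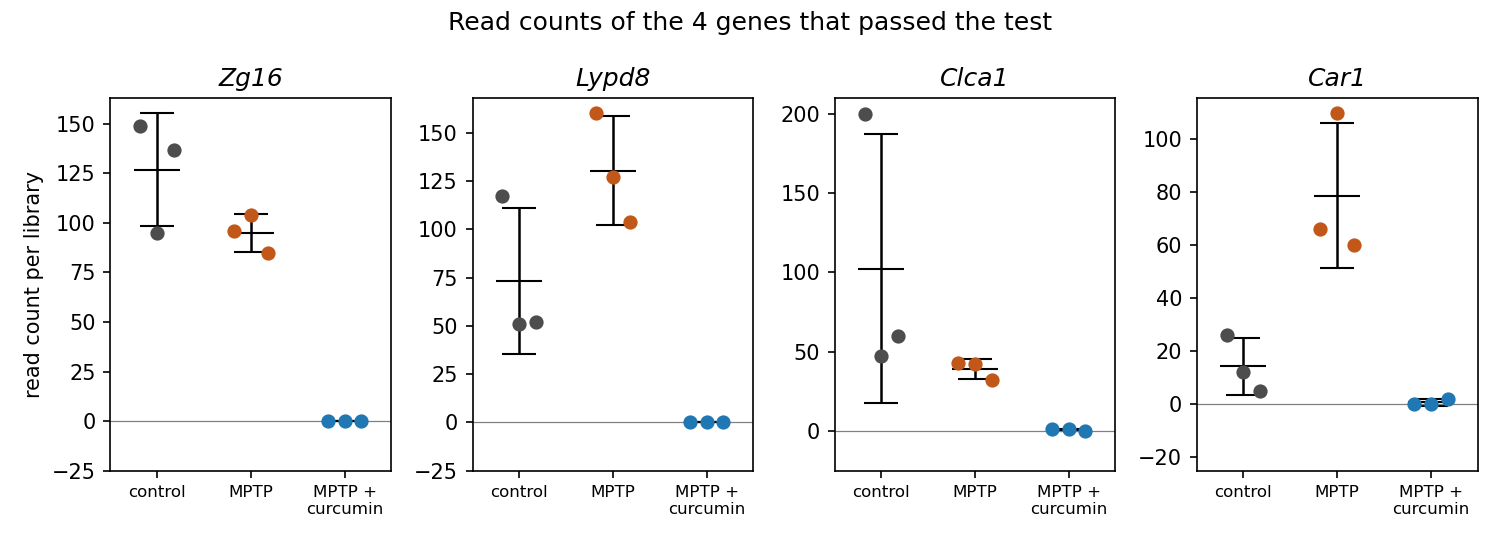
Read counts of Zg16, Lypd8, Clca1 and Car1 in each library (points), with the group mean and SD over 3 libraries (bars). The MPTP + curcumin libraries held 0 to 2 counts of each gene, and every other library held at least 5.

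All 7 erythroid genes were negative and the list fell (camera adjusted p = 1.21e-15, adjusted p = 0.254 with an estimated correlation), with 5 members lower adjusted over the list alone. Hba-a1 stood at 83.4 ± 30.2 CPM with curcumin and 160.2 ± 8.03 in MPTP (SD, n = 3 each), a log2 fold change of −0.94 ± 0.19 (SE). That of Hbb-bs was −0.94 ± 0.20. Car1, which is not in the list, was at −6.65 ± 0.90, and in MPTP against control at 2.46 ± 0.61 (edgeR adjusted p = 0.531). Against control with curcumin it was at −4.19 ± 0.98 (adjusted p = 0.521), where the erythroid median was 0.06. Without MPTP + curcumin 1, the count of called genes was 9 and included Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Alas2.

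Among vascular and stromal lists, meningeal fibroblast genes fell by a median of −0.29 (camera adjusted p = 1.36e-06, adjusted p = 0.655 with an estimated correlation). Slc6a13, a GABA transporter of the meninges, had a log2 fold change of −0.72 ± 0.19 (SE) and Ogn, a matrix proteoglycan, of −0.62 ± 0.24. Of this list 1 member was lower adjusted over the list alone, 2 without MPTP + curcumin 1 and 4 without MPTP + curcumin 2 (medians −0.20 and −0.32), and 0 without MPTP 1, MPTP 3 or MPTP + curcumin 3 (medians −0.30, −0.20 and −0.25). Mural cell genes, all 8 negative, fell by −0.16 (adjusted p = 0.000713, adjusted p = 0.528 with an estimated correlation). The mural call was lost without MPTP + curcumin 1 (median −0.09), and the median was −0.24 without MPTP + curcumin 3.

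The lists of NF-kB and interferon genes were lower too. Those of activated microglia and reactive astrocytes were not called, with medians of −0.04 and −0.03 (camera adjusted p = 0.678 and 0.469). NF-kB and cytokine genes had 13 of 17 members negative, a median of −0.21 and a mean of −0.48, and fell (camera adjusted p = 0.0029, adjusted p = 0.528 with an estimated correlation). Ccl2, a monocyte chemoattractant, stood at 0.0732 ± 0.0141 CPM with curcumin and 0.567 ± 0.184 in MPTP (SD, n = 3 each) and was the 1 member lower adjusted over the list alone. It was not without MPTP 1, MPTP 2 or any single MPTP + curcumin library. The mean of Ccl2 with curcumin lay under the floor of 3 counts per library, 0.0827 CPM, so that level is uncertain. The NF-kB call was lost without MPTP + curcumin 2 (median −0.17), and the median was −0.12 without MPTP 3, −0.25 without MPTP 1 or MPTP + curcumin 3, −0.30 without MPTP 2 and −0.46 without MPTP + curcumin 1. Interferon response genes fell by −0.19 (adjusted p = 0.00236, adjusted p = 0.766 with an estimated correlation), with Ifitm3, an antiviral membrane protein, at −0.33 ± 0.16. The interferon call was lost without MPTP 3 (−0.04), and the median was −0.30 without MPTP 1.

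The stress and ribosomal lists rested on single libraries. Glucocorticoid genes fell by −0.15 (camera adjusted p = 0.0012, adjusted p = 0.766 with an estimated correlation). The median was 0.02 without MPTP + curcumin 1, where the call was lost, and −0.28 and −0.26 without MPTP + curcumin 2 and 3. Unfolded protein response genes rose by 0.15 (adjusted p = 0.00959, adjusted p = 0.766 with an estimated correlation), a call lost without MPTP + curcumin 1 (0.05). Cytosolic ribosomal protein genes fell by −0.08 (adjusted p = 1.27e-05, adjusted p = 0.815 with an estimated correlation). The ribosomal call was lost without MPTP 3 (−0.03) and MPTP + curcumin 1 (0.01), the median was −0.18 without MPTP + curcumin 2, and it was 0.07 without control 3, MPTP 3 and MPTP + curcumin 1, where the list was called in the opposite direction.

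Hypothalamic neuropeptide genes fell by −0.82 (camera adjusted p = 0.0461, adjusted p = 0.766 with an estimated correlation), with Trh, the thyrotropin-releasing hormone, at a log2 fold change of −1.40 ± 0.62 and Pmch at −2.36 ± 1.76. The hypothalamic call was lost without MPTP 3 (median −0.11), and without MPTP + curcumin 1, 2 or 3 (adjusted p = 0.077, 0.161 and 0.163). Cerebellum and hindbrain genes rose by 0.25 (adjusted p = 0.000713, adjusted p = 0.764 with an estimated correlation), with Hoxd3, a hindbrain patterning gene, at 0.54 ± 0.31. That call was lost without MPTP 3 (0.14) and MPTP + curcumin 3 (0.16). None of the members of the region, mural, interferon, glucocorticoid, unfolded protein or ribosomal lists passed when adjusted over the list alone.

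The PI3K-AKT core list rose by 0.06, with 27 of 34 members positive (camera adjusted p = 0.0461, adjusted p = 0.815 with an estimated correlation). The call was lost without MPTP 3 (median 0.03), MPTP + curcumin 1 (0.02) and MPTP + curcumin 3 (0.06), and the median was 0.10 without MPTP 2 and 0.11 without MPTP + curcumin 2. Without control 3, MPTP 3 and MPTP + curcumin 1 together it was −0.01 (adjusted p = 0.371). Akt1 was at 0.04 ± 0.07 (SE), Akt2 at −0.02 ± 0.10, Pik3ca at 0.05 ± 0.07 and Pik3r1 at 0.06 ± 0.08. Eif4ebp1, a repressor of translation that the pathway inactivates, was at −0.52 ± 0.28. The ligand and receptor list had a median of 0.04 (adjusted p = 0.486), and 0 members of either list passed when adjusted over the list alone.

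Th was at −0.27 ± 0.32 and Slc6a3 at 0.30 ± 1.19 on the log2 scale (SE), Slc18a2 at −0.18 ± 0.26, Ddc at −0.09 ± 0.20, Gfap at −0.04 ± 0.16 and Aif1 at −0.06 ± 0.27. The dopaminergic list had a median of 0.14 and a mean of 0.11, while camera's direction was down (adjusted p = 0.709). Without MPTP + curcumin 1 its median was −0.36 and the list was called (adjusted p = 0.000469). That call used the preset correlation, and with an estimated one camera's adjusted p over all libraries was 0.989.

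Besides the 3 genes called by edgeR, 392 of 15461 had an unadjusted p under 0.05 where chance gives 773, and DESeq2 called 14 genes and voom 3. The groups did not overlap in 1137 genes, 7.35%, where chance gives 10%. The count was 16 without control 3, MPTP 3 and MPTP + curcumin 1. Of 37 lists 11 were called, 3 higher and 8 lower, and 0 with an estimated correlation or with fry. No gene was called in both this comparison and MPTP against control with opposite direction by edgeR or voom, and 4 were by DESeq2 (Alas2, Car1, Hba-a1 and Ube2l6). Without MPTP + curcumin 1, 6 were (Alas2, Hba-a1, Hba-a2, Hbb-bs, Hbb-bt and Ube2l6). The log2 fold changes of both comparisons correlated at −0.474 across genes, with a covariance of −0.0621. Unchanged groups that share the MPTP libraries gave a mean correlation of −0.50 over 20 simulations, with a range from −0.54 to −0.46, and a mean covariance of −0.0451, with a range from −0.0509 to −0.0423. Signs were opposite in 70.9% of genes, against 66.1% to 67.1% in the simulations. The simulated genes varied independently of one another, while real genes move together, with an estimated correlation of 0.836 in the ribosomal list. The simulated ranges leave that out, so they cannot decide whether the observed values exceed chance.

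The comparison of MPTP + curcumin with control sets both treatments together against untreated mice. Zg16, Lypd8 and Clca1, a secreted protein of goblet cells, were lower in the MPTP + curcumin libraries and were the 3 genes called. Glucocorticoid-responsive and immediate early genes were lower than in control as lists here too, by medians of −0.66 and −0.54 (adjusted p = 0.166 and adjusted p = 0.412 with an estimated correlation). MPTP against control uses the same control libraries, so these shifts are not independent findings. The erythroid list was not called against control.

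Zg16 had 3.54 ± 0.871 CPM in control (SD, n = 3) and 0 counts with curcumin, at least 42.7-fold lower (edgeR adjusted p = 0.000563). Lypd8 had 2.03 ± 1.05 CPM and 0 counts, at least 24.6-fold lower (adjusted p = 0.00975). Clca1 (NCBI gene 23844, chromosome 3, 145004537 to 145032776) had 307 counts in the control libraries and 2 with curcumin, a ratio of 154 (95% interval 42.4 to 1280; adjusted p = 0.0148). Control 1 held 200 of those counts, against 47 and 60 in control 2 and 3. The log2 fold change of Clca1 was −7.03, and −6.1 without control 1 (edgeR adjusted p = 0.0178). Each of the 3 genes was lower in 3 of 3 libraries. The Clca1 call was lost without MPTP + curcumin 2 (adjusted p = 0.113) and 3 (0.147) and with limma voom (0.278). Its log2 fold changes there were −7.39, −6.52 and −6.32. In a fit of only the 6 libraries Zg16 alone was called, with Lypd8 and Clca1 both at an adjusted p of 0.119. Zg16 and Lypd8 were lower in both curcumin comparisons, which share the MPTP + curcumin libraries and so are not independent findings. Simulated unchanged groups that share them gave 0.05 such genes on average. Independent lists would give 0.000582, a figure that leaves out the sharing. Car1 had 43 counts in control, a ratio of 21.6 (95% interval 5.63 to 184) that did not pass (adjusted p = 0.521).

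All 16 glucocorticoid-responsive genes were negative and the list fell (camera adjusted p = 3.2e-28, adjusted p = 0.166 with an estimated correlation), with 11 members lower adjusted over the list alone. Fkbp5, a chaperone of the glucocorticoid receptor, stood at 24.0 ± 2.85 CPM with curcumin and 39.4 ± 6.22 in control (SD, n = 3 each), a log2 fold change of −0.72 ± 0.13 (SE). Errfi1 was at −0.49 ± 0.08, Cdkn1a at −0.96 ± 0.17 and Zbtb16 at −1.60 ± 0.29. Without control 2, Zbtb16 and Serpina3f, a serine protease inhibitor, were also called over all genes, which made 5. All 17 immediate early genes were negative and the list fell (adjusted p = 4.32e-10, adjusted p = 0.412 with an estimated correlation), with Egr4 at −1.10 ± 0.32, Nr4a1 at −1.06 ± 0.31 and Fos at −1.36 ± 0.42. Adjusted over the list alone 6 members were lower, 1 without MPTP + curcumin 2 (median −0.56), and 0 without control 1 (median −0.31), MPTP + curcumin 1 (−0.42) or MPTP + curcumin 3 (−0.48). Unfolded protein response genes fell by −0.20 (adjusted p = 0.000416, adjusted p = 0.582 with an estimated correlation), a call lost without control 1 (−0.06). The median was −0.32 without control 2, where 10 members were lower adjusted over the list alone, and −0.22 without MPTP + curcumin 1, where 5 were, against 0 with all libraries.

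NF-kB and cytokine genes fell by −0.47, with 14 of 17 negative (camera adjusted p = 0.000129, adjusted p = 0.349 with an estimated correlation). Ptgs2, cyclooxygenase 2, stood at 2.40 ± 0.120 CPM with curcumin and 5.18 ± 1.44 in control (SD, n = 3 each), and 1 member of the list was lower adjusted over the list alone. That number was 0 without control 1 (median −0.58) and control 3 (−0.19), 4 without control 2 (−0.58) and 2 without MPTP + curcumin 2 (−0.33). Reactive astrocyte genes fell by −0.47 (adjusted p = 0.00131, adjusted p = 0.438 with an estimated correlation). Hspb1, a small heat shock protein, was at −0.91 ± 0.24 and Osmr, a cytokine receptor, at −0.77 ± 0.25. The astrocyte call was lost without MPTP + curcumin 1 (median −0.46), and the median was −0.29 without control 1, −0.17 without control 3 and −0.30 without MPTP + curcumin 2. Adjusted over the list alone 1 astrocyte gene was lower, 5 without control 2 (median −0.57), and 0 without control 1, MPTP + curcumin 2 or MPTP + curcumin 3 (median −0.52). Interferon response genes fell by −0.19 (adjusted p = 0.00395, adjusted p = 0.638 with an estimated correlation), a call lost without control 1 (−0.08) and MPTP + curcumin 1 (−0.19), and 1 member was lower adjusted over the list alone without control 2 (−0.26).

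Meningeal fibroblast genes, all 13 negative, fell by −0.25 (camera adjusted p = 0.000547, adjusted p = 0.62 with an estimated correlation). Col3a1, a fibrillar collagen, was at −0.80 ± 0.28 (SE). The meningeal call was lost without control 1 (median −0.03) and MPTP + curcumin 1 (−0.19), and the median was −0.47 without control 2. Adjusted over the list alone 0 meningeal genes were lower, 4 without control 2 and 1 without MPTP + curcumin 2 (median −0.32). Mural cell genes, all 8 negative, fell by −0.19 (adjusted p = 0.00101, adjusted p = 0.428 with an estimated correlation), a call lost without MPTP + curcumin 1 (−0.10). Ependymal genes, all 9 positive, rose by 0.23 (adjusted p = 0.00911, adjusted p = 0.582 with an estimated correlation), with Foxj1, a regulator of motile cilia, at 0.23 ± 0.13. The ependymal call was lost without control 2 (0.22) and MPTP + curcumin 3 (0.14).

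Cytosolic ribosomal protein genes rose by 0.08 (camera adjusted p = 0.000852, adjusted p = 0.797 with an estimated correlation), a call lost without control 2 (median 0.05) and MPTP + curcumin 2 (−0.02), with medians of 0.13 without control 3 and 0.16 without MPTP + curcumin 1, where 2 members were higher adjusted over the list alone. Complex I genes rose by 0.05 (adjusted p = 0.032, adjusted p = 0.844 with an estimated correlation), a call lost without control 2 (0.01), MPTP + curcumin 2 (−0.02) and MPTP + curcumin 3 (0.04), with medians of 0.09 without control 1 and 0.13 without MPTP + curcumin 1. Apoptosis and p53 genes fell by −0.07 (adjusted p = 0.00583, adjusted p = 0.412 with an estimated correlation), a call lost without MPTP + curcumin 1 (−0.04), with medians of −0.10 and −0.03 without control 2 and 3 and −0.11 without MPTP + curcumin 2. Circadian clock genes fell by −0.04 (adjusted p = 0.00749, adjusted p = 0.582 with an estimated correlation). Per2, a clock gene that glucocorticoids also induce, stood at 23.8 ± 3.27 CPM with curcumin and 36.8 ± 3.33 in control (SD, n = 3 each). The clock call was lost without control 2 (−0.05) and MPTP + curcumin 1 (−0.03), and the median was −0.09 without control 1, −0.07 without MPTP + curcumin 2 and −0.11 without MPTP + curcumin 3.

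The PI3K-AKT core list was not called, with 22 of 34 members negative and a median of −0.03 (camera adjusted p = 0.0694). It was called without control 3 (−0.04, adjusted p = 0.0242) and without MPTP + curcumin 1 (−0.07, adjusted p = 0.00179). Calls without a library used the preset correlation, and with an estimated one camera's adjusted p over all libraries was 0.797. Akt1 was at −0.03 ± 0.07 (SE), Akt2 at −0.05 ± 0.10, Pik3ca at −0.04 ± 0.07 and Pik3r1 at 0.03 ± 0.08. The dopaminergic list had a median of −0.04 (adjusted p = 0.153), and was called without control 1 (−0.22, adjusted p = 0.00587) and MPTP + curcumin 1 (−0.56, adjusted p = 5.92e-05). For the dopaminergic list, too, the adjusted p over all libraries with an estimated correlation was 0.797. Th was at −0.14 ± 0.32, Slc6a3 at 0.18 ± 1.19, Slc18a2 at −0.22 ± 0.26, Ddc at −0.04 ± 0.20, Gfap at −0.03 ± 0.16 and Aif1 at 0.41 ± 0.27. The erythroid list had a median of 0.06 (adjusted p = 0.837, adjusted p = 0.975 with an estimated correlation), and was lower without MPTP + curcumin 1 (−0.28, adjusted p = 0.00926 at the preset correlation).

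Here 553 of 15461 genes had an unadjusted p under 0.05 where chance gives 773, and DESeq2 called 35 genes and voom 2. The groups did not overlap in 1125 genes, 7.28%, where chance gives 10%. The count of called genes was 5 without control 2, 5 without MPTP + curcumin 1 and 17 without control 3, MPTP 3 and MPTP + curcumin 1. Of 37 lists 13 were called, 3 higher and 10 lower, and 0 with an estimated correlation or with fry. The log2 fold changes of this comparison and of MPTP against control correlated at 0.388 across genes, with a covariance of 0.0486, where unchanged groups sharing the controls gave means of 0.497 and 0.0448. The simulated correlations ran from 0.463 to 0.527 and the covariances from 0.0398 to 0.0503. Signs were equal in 71.1% of genes, against 66% to 67.4% in the simulations. Here too the simulated genes varied independently, so these ranges cannot decide whether the observed values exceed chance.

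The remaining lists were called in no comparison. In MPTP against control, in MPTP + curcumin against MPTP and in MPTP + curcumin against control, the medians were −0.08, 0.04 and 0.06 for FOXO targets, 0.06, −0.03 and 0.01 for NRF2 targets, and −0.01, −0.01 and 0.01 for genes of familial Parkinson disease. In the same order they were 0.02, −0.04 and 0.01 for striatal projection neurons, −0.11, 0.06 and −0.06 for cortical and hippocampal excitatory neurons, 0.05, −0.19 and −0.13 for thalamic neurons, and 0.04, 0.03 and −0.05 for GABAergic interneurons. Astrocytes had −0.01, −0.01 and 0.04, mature oligodendrocytes 0.01, 0.00 and 0.05, oligodendrocyte precursors −0.02, −0.09 and 0.02, activated microglia 0.10, −0.04 and −0.05, and endothelial cells −0.03, 0.10 and 0.07. Choroid plexus genes had −0.03, −0.05 and −0.07, blood leukocyte genes −0.16, 0.12 and −0.06, and proliferation and neuroblast genes −0.13, 0.04 and 0.07. Adjusted over the list alone, 2 FOXO targets were lower in MPTP against control and 3 in MPTP + curcumin against control (mean −0.05). Mature oligodendrocyte genes had 2 and 1 higher there, and endothelial genes 1 higher and 1 lower in each. Lower were also 1 oligodendrocyte precursor gene in MPTP against control and 1 GABAergic gene in MPTP + curcumin against MPTP. Activated microglia had 1 higher and 1 lower in MPTP + curcumin against control. Median, mean and camera's direction differed in sign in 1 or more comparisons for the dopaminergic, striatal, cortical, thalamic, hypothalamic, GABAergic, astrocyte, oligodendrocyte precursor, activated microglia, meningeal fibroblast, blood leukocyte, choroid plexus, proliferation, FOXO, familial Parkinson disease, interferon and PI3K-AKT ligand lists. None of these lists was called in the comparison where its signs differed.

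Leaving out 1 library, in fits that used the preset correlation only, brought calls to lists that were otherwise not called. In MPTP against control these were thalamic neurons (0.25) and hindbrain (−0.10) without control 3, mature oligodendrocytes (0.08), meningeal fibroblasts (0.23), choroid plexus (0.34) and the clock (−0.09) without control 1, reactive astrocytes without control 2 (−0.21) or MPTP 3 (−0.21), oligodendrocytes without MPTP 1 (0.04), and hypothalamic neuropeptides without MPTP 2 (0.95). In MPTP + curcumin against MPTP, without MPTP 1 or MPTP 2, they were thalamic neurons (−0.30 and −0.25), homeostatic microglia (−0.09 and −0.15), the synapse (0.08 and 0.10) and cholesterol synthesis (−0.09 for both), and ependymal cells without MPTP 2 (−0.35). Without MPTP 3 they were oligodendrocytes (0.10) and endothelial cells (0.12). Without MPTP + curcumin 1 they were thalamic neurons (−0.24), choroid plexus (0.24), blood leukocytes (0.62), complex I (0.06) and cholesterol synthesis (−0.09). Without MPTP + curcumin 2 they were homeostatic microglia (−0.13), NRF2 targets (−0.06), complex I (−0.09) and the synapse (0.14), and without MPTP + curcumin 3 choroid plexus (−0.25), ependymal cells (−0.29) and the clock (−0.12). In MPTP + curcumin against control, without control 1, 2 or 3, choroid plexus was called at 0.29, −0.24 and −0.23. Without control 1 or control 2 so were thalamic neurons (−0.24 and −0.27) and hindbrain (0.16 and 0.17). Others were oligodendrocytes (0.14) and the synapse (−0.09) without control 1, cholesterol synthesis without control 2 (0.05) and homeostatic microglia without control 3 (0.16). Without MPTP + curcumin 1 they were thalamic neurons (−0.30), hindbrain (0.26), choroid plexus (0.19), blood leukocytes (0.47) and the synapse (−0.15), and without MPTP + curcumin 3 oligodendrocytes (0.09), homeostatic microglia (0.10) and choroid plexus (−0.32).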

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

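Leaving out the 3 libraries high in hypothalamic and midbrain markers and the dopaminergic covariate were tests chosen only after results had been seen. Genes called in MPTP against control, 0 by edgeR with 957 at an unadjusted p under 0.05, were 38 with DESeq2, 11 in a fit of only the 6 libraries compared, 21 without the 3 libraries and 15 with the covariate, and those over 2-fold were 11, 3, 4 and 4. Voom, RLE, library totals, both filters, robust estimation and FPKM also gave 0 there. In MPTP + curcumin against MPTP, 3 genes became 6 with no filter, 14 with DESeq2, 6 with the 6 libraries, 5 with FPKM and a pseudocount of 1, 16 without the 3 libraries and 16 with the covariate. Over 2-fold they were 6, 11 and 6 for the first 3 of these settings, and 16 and 10 for the last pair. In MPTP + curcumin against control, 3 genes became 35 with DESeq2, 1 with the 6 libraries, 1 with FPKM and a pseudocount of 1, 17 without the 3 libraries and 7 with the covariate, and those over 2-fold were 19, 1, 1 and 5 for the first 4. Genes opposite in MPTP against control and MPTP + curcumin against MPTP, 0 by edgeR, were 4 with DESeq2, 9 without the 3 libraries and 6 with the covariate.

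Gene lists called, 12, 11 and 13, were 0 in each comparison with an estimated inter-gene correlation and 0 with fry. The ribosomal list in MPTP + curcumin against MPTP, at −0.078, was 0.068 (adjusted p = 2.48e-05) without the 3 libraries. For all of these changes the cause was not tested. With 1 library of the comparison left out, called genes ranged from 0 to 2 in MPTP against control (17 without MPTP + curcumin 1, which shares only the fit), 2 to 9 in MPTP + curcumin against MPTP and 2 to 5 in MPTP + curcumin against control. Those over 2-fold ranged from 0 to 1, 2 to 9 and 2 to 5, opposite genes, over all 9 libraries left out in turn, from 0 to 6, and lists from 10 to 17, 8 to 16 and 11 to 16. Over all settings, 3351 values of named genes kept direction and side of the threshold, 46 passed it newly, 14 no longer passed, 88 moved and 0 reversed. Of list values 1058 were kept, 72 passed newly, 128 no longer passed, 184 moved and 1 reversed.

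Libraries that share a replicate number did not deviate together. Their 9 correlations ran from −0.137 to 0.18, 1 of them over 0.1 (control 2 with MPTP 2). In both other groups at once, 0 libraries correlated best with their own number. With the replicate number as a block, 0, 2 and 3 genes and 14, 13 and 14 lists were called in the 3 comparisons. Depth limits the colon genes: a count of 0 allows up to 0.0861 CPM in the shallowest library.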

Other observations

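The tests on colon, liver, clock and KEGG genes, region correlations, Slc6a3 range, expected Zg16 counts, splits and the fit without 3 libraries were chosen only after the results they bear on had been seen. The 3 genes in the next paragraph and the use of single left-out libraries to weigh an explanation were likewise chosen afterwards, while those fits, DESeq2, FPKM, the 6-library fit, the estimated correlation and fry were fixed in advance.

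Ube2l6, an enzyme of the interferon-induced ISG15 system, had 300, 309 and 300 counts in the control libraries, 513, 582 and 617 in MPTP, and 396, 276 and 265 in MPTP + curcumin. Its log2 fold changes were 0.92 ± 0.15 (SE) in MPTP against control (edgeR adjusted p = 0.177) and −0.89 ± 0.15 in MPTP + curcumin against MPTP (adjusted p = 0.136), and DESeq2 called both. These comparisons share the MPTP libraries, so the calls are not independent. Reg3b, an antibacterial lectin of gut and pancreas, had 126, 199 and 52 counts in MPTP and 8, 0 and 1 with curcumin, and did not pass (adjusted p = 0.38). A1bg, a plasma glycoprotein, had 168, 147 and 68 counts with curcumin, 24 in control 2 and 0 in the other 5 libraries (adjusted p = 0.38 against MPTP). It was called higher against MPTP in a fit of only the 6 libraries compared and with FPKM and a pseudocount of 1.

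Of 321 KEGG pathways with at least 10 tested genes, camera called 20 in MPTP against control, 3 in MPTP + curcumin against MPTP and 7 in MPTP + curcumin against control. With an estimated correlation 0 were called, the smallest adjusted p being 0.613, 0.835 and 0.93. Protein processing in the endoplasmic reticulum fell in MPTP against control, with 117 of 161 genes lower (adjusted p = 0.00197, adjusted p = 0.613 with an estimated correlation). Retinol metabolism rose in MPTP + curcumin against control, with 30 of 40 genes higher and a median of 0.22 (adjusted p = 0.002, adjusted p = 0.93 with an estimated correlation). In that comparison the added list of liver genes had a median of 0.36, with 4 of 17 lower. Whether the pathway's shift arose in brain cells was not tested. The KEGG PI3K-Akt pathway, with 304 genes, was not called (adjusted p = 0.284, 0.784 and 0.637). Neither was the KEGG dopaminergic synapse, with 126 genes (0.448, 0.209 and 0.818).

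Zg16, Lypd8, Clca1 and Car1, the last also a gene of red blood cells, were near 0 in the MPTP + curcumin libraries, and of 28 genes written as a colon epithelium list, 14 besides the called 4 were tested, and the 9 not seen before were lower against both groups, 9 of 9, with sums of 102 to 133 counts against 208 to 345, so traces of colon RNA in the control and MPTP libraries may account for part of this. Their median in MPTP against control was 0.46, with Fcgbp at −0.26, 3 of the 9 kept at least 10 counts in each curcumin library, Vil1 had 18, 37 and 16 there against 24 to 52 elsewhere, Slc26a3 6, 8 and 11 against 5 to 14, and Aqp8, too low to be tested, had 7, 4 and 9 counts with curcumin, 2, 1 and 4 in MPTP and 17, 1 and 9 in control. The count of 9 of 9 goes by sign alone, both comparisons share the MPTP + curcumin libraries, and the share over all genes is not given here. Genes such as Agr2, with 8, 0 and 0 counts with curcumin, passed the filter only through the other libraries. The count is therefore weak evidence. A general lack of RNA from other organs was weighed with liver genes, without Ttr and Trf, which brain also makes. Their sums with curcumin were 2796 to 5375 counts, against 147 to 6310 in the other libraries. Liver RNA was thus not lacking with curcumin, which argues against a lack that includes liver, the only other organ examined. The sums with curcumin passed a bound of 257, but that bound was set after the sums were seen. It replaced a comparison with the median of the other libraries, 3023.5, which decided nothing. Control 3 and MPTP 1, with 218 and 147, lie below the bound, so passing it decides little. Depth is argued against by at least 92.7 Zg16 counts expected per library. An effect of curcumin stays open and was not tested. It cannot be told apart from daily gavage, which is described here only for the MPTP + curcumin group.

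Glucocorticoid-responsive genes were lower than control as a list in both groups given MPTP, a call lost in both with an estimated correlation (adjusted p = 0.354 and 0.166) and with fry (adjusted p = 0.308 and 0.241). Both comparisons use the same control libraries and so are not independent findings. A single control library as the cause is argued against by a median of −0.43 without control 3 in MPTP against control. The region of the dissected piece stays open there. Without the 3 libraries high in hypothalamic and midbrain markers the median was −0.43, but the hindbrain list still separated the groups. Its means were 6.18 and 6.04 log2 CPM in control 1 and 2 and 5.85 and 5.78 in MPTP 1 and 2. MPTP + curcumin 2 and 3 had 6.21 and 6.20, with glucocorticoid means of 4.94 and 4.90 against 5.38 and 5.28 in control 1 and 2. Time of day at death stays open and cannot be told apart from treatment: 7 clock output genes shifted against 4 of the opposite phase by 0.10 log2 in MPTP, within an SD of 0.11, and by −0.08 in MPTP + curcumin, where library 1, with the lowest mean of the glucocorticoid list (4.23 log2 CPM), stood at 1.11 against 1.42 to 1.68 in the other libraries. For immediate early genes a single control library stays open, with a median of −0.36 without control 1. An effect of MPTP stays open and was not tested. It cannot be told apart from probenecid or the repeated injections, which the control group did not receive by its label.

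Dopaminergic markers spread widely within groups. The region of the dissected piece may account for this, since over 9 libraries 2 of 5 region lists correlated with the dopaminergic list by r at an adjusted p under 0.05, and 1 by rho. Hindbrain had r = −0.811 (exact two-sided p = 0.00829, adjusted 0.0266) and rho = −0.833 (exact p = 0.00827, adjusted 0.0413), and −0.767 without the 2 farthest libraries, while cortex had r = 0.778 (exact p = 0.0106, adjusted 0.0266), rho = 0.733 (exact p = 0.0311, adjusted 0.0519), and 0.587. The hypothalamic list was tried first, alone, and decided nothing (r = 0.470, exact p = 0.209), the thalamic list had r = 0.647 (exact p = 0.0618, adjusted 0.103), rho = 0.767 (exact p = 0.0214, adjusted 0.0519) and 0.767 without the 2 farthest, and the striatal list r = −0.024 and rho = 0.067. Loss of neurons after MPTP as the cause of the spread is argued against by control libraries, which differed 43.7-fold in Slc6a3 CPM against 2.1-fold in MPTP, and whether MPTP lowered dopaminergic markers stays open.

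The 6 libraries of a comparison make 10 splits into groups of 3, too few for a share under 0.05. In MPTP against control the real count of genes was 0, which every split reaches, so the splits say nothing about genes there (highest other 0), and 3 splits gave at least the real 12 lists, with 17 as the highest other. In MPTP + curcumin against MPTP 1 split, the real one, gave 3 genes, all over 2-fold, with 0 as the highest other, and 4 gave at least 11 lists, with 16 as the highest other. In MPTP + curcumin against control 2 splits gave at least 3 genes and 2 gave at least 3 over 2-fold, with 15 and 12 as the highest other, and 5 gave at least 13 lists, with 16 as the highest other. The split with 15 genes set control 1 and MPTP + curcumin 2 and 3 against control 2 and 3 and MPTP + curcumin 1, which points to a structure of the samples. That split also separated libraries low and high in dopaminergic markers. The list means were 2.78, 2.68 and 2.73 log2 CPM on the first side and 3.44, 3.82 and 4.13 on the second.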
